A study of Mus musculus with 12 samples.

How the data were processed

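Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in macrophages (myeloid cells) taken from the spleens of 4-day-old C57BL/6 mouse pups. Per the labels' protocols, libraries were made with the Omni-ATAC procedure. The labels give 4 groups of 3 libraries: wild-type or Il27ra knockout pups, each without infection or 24 h after infection with Escherichia coli O1:K1:H7. Nothing in the labels says whether the libraries of a group came from separate animals, so the p-values below measure only the spread between these libraries, which may be technical. The titles give the genotypes separate runs of library numbers. Genotype and library series cannot be told apart in any comparison of the genotypes.

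Per the submitters' processing notes, Bowtie2, MACS3 and the mm10 build were used; their versions, the settings and any adapter shift of the reads are not given in the sources used here. The deposited lists hold 1 set of peaks per library, so the peaks used here were called on each library. Whether pooled replicates were called too is not given in the sources used here. Each peak carries a fold enrichment over the library's own background, a ratio given by the authors' peak caller, and a −log10 p and −log10 q, also from the authors' peak caller. The score deposited beside each peak was 10 times its −log10 q, and the deposited offset gave its summit. All of these values per peak are the authors', and they were used here to rank, filter or describe peaks within a library and to recover its background and summit heights. The lowest −log10 q in each deposited list lay just above 3.

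Each of the 12 lists analysed here ended part-way through a line, at a different place in the genome, and that last line was left out. Comparisons over all 12 libraries were therefore made in the part of the genome that every list covered: chromosomes 1, 10 and 11, and chromosome 12 up to position 108494522. This part held 126803 peaks. The Il27ra locus (chr8:84030294-84042589) lay outside the reach of every list and was not analysed here, so the genotype labels were not checked on the targeted gene. The annotation was GENCODE vM21, whose build matches mm10. No genome sequence was used here, so the planned test of transcription factor motifs was not run.

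The number of reads per library is not given in the sources used here, so sequencing depth is unknown. Fold enrichment and −log10 p together gave a whole number of fragments at the summit for 100% of peaks in every library (tolerance 0.0001), against 0.0213% to 1.27% when the fold was moved by 0.5%. From this, the background was taken as the most frequent value among the peaks of a library, held by 2.06% to 9.97% of them. It lay between 0.44 and 0.902 fragments per position, and the median summit height between 19 and 29 fragments.

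Peaks of the 12 libraries were merged where they overlapped by 1 bp or more, and merged regions called in at least 2 libraries were kept, which gave 16179 regions with a median width of 217 bp. A region was called gained if every infected and no uninfected library had a peak in it, and lost in the opposite case. Regions called in only 1 genotype were defined in the same way. Beside these counts, an exact conditional test stratified by genotype was run per region. A region was placed at a promoter if it lay within 1 kb of a transcription start site, and otherwise in an exon, an intron or between genes. Pairs of libraries were compared by the Jaccard index, the shared share of all regions called in either. Peak number, covered length, median width and promoter share per library were compared by exact two-sided permutation tests, with infection labels permuted within genotype (400 labelings) and genotype labels 6 against 6 (924 labelings).

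Fold enrichment is relative to each library, so only its rank was compared. The 3598 regions called in all 12 libraries were ranked within each library, and the ranks were turned into normal scores. Scores were fitted with limma (4 group means, trended empirical Bayes) and adjusted by the Benjamini-Hochberg method over the 3598 regions. A rank shift is a difference in normal score, where 1 is about 1 SD of all regions, and a percentile is the rank of a region among these 3598, from 0 for the lowest fold enrichment to 100 for the highest. A shift in rank is relative to the other shared regions and is not a change in read density.

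The 18 gene lists fixed beforehand were interferon-stimulated genes, type II interferon and GBP genes, inflammatory cytokines and chemokines, NF-kB feedback and early response genes, the IL-27 and STAT3 pathway, acute phase and innate defence, neutrophil granule genes, and macrophage and monocyte identity. The others were phagocytosis and lysosome, MHC class II and co-stimulation, glycolysis and hypoxia, erythroid markers, B cell markers, T cell and NK cell markers, megakaryocyte and platelet markers, endothelial and stromal markers, cell cycle genes and housekeeping genes. They were tested by limma's camera on 1 promoter region for each of 2185 genes, with an inter-gene correlation of 0.01 and again with an estimated one. Camera was run on lists with at least 2 such promoters, a minimum set after the data were seen, and p-values were adjusted over all 18 lists. The peaks in each list's loci (gene body plus 5 kb upstream), per 10000 peaks of the library with 0.5 added to each count, were compared by an exact two-sided permutation test within genotype.

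The regions and genes named were chosen by a rule. For infection averaged over the genotypes, it took up to 10 promoter regions with the largest rise and 10 with the largest fall in mean percentile among those past an adjusted p of 0.05. For each other contrast it took the 5 largest each way. Among gained, lost and genotype-restricted regions it took the 10 or 5 with the highest mean percentile of fold enrichment in the libraries that called them. Up to 4 members of each list were named. Regions are named by the gene that holds them, or else by the nearest start site within 50 kb, or otherwise by position. Predicted genes were passed over, and some genes that the rule names are not reported here. The groups, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were a stricter −log10 q of 8, lists of equal length, a 50% overlap, 500 bp windows around summits, other ranked values, a subset of regions, a replicate block, robust weights, narrower promoters, wider loci and the omission of each library. Another 4 alternatives were chosen after seeing the data: 9 libraries with longer reach (up to chr2:103866044), adjustment of the ranks for region width and promoter status, peak number as a covariate, and adjustment over the lists with 3 or more members. The 9 libraries leave out wild-type infected library 3, knockout infected library 2 and wild-type uninfected library 2. These held the most peaks in the shared part (15834, 14147 and 12268), so that setting also changes the peak numbers.

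On simulated scores for the infection contrast over 3598 regions, the rank test recovered 24.5%, 97.5% and 99.5% of 200 regions shifted by 0.5, 1 and 1.5, with 2, 8 and 11 other regions called. The simulated noise was independent between regions, and other splits of the real libraries called up to 123 regions for this contrast. The simulation therefore gives no error rate for these libraries. On simulated calls over 16179 regions, all 200 regions made to be gained in both genotypes were recovered, with 4 others. That recovery was fixed by how the regions were made, so it checks the code and measures no sensitivity. The other calls were drawn independently for each library, without any structure shared between regions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.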

Results

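The study asked how interleukin-27 shapes the response of the newborn to sepsis, and the libraries analysed here show where chromatin was open in spleen macrophages with and without Il27ra. Il27ra is the IL-27-binding chain of a receptor that signals through STAT3, among others. The 12 libraries formed 4 groups of 3, wild-type and knockout pups with and without infection, and between 6892 and 15834 peaks per library lay in the shared part of the genome. Of the 16179 merged regions, 21.1% lay at promoters, 38.4% in introns and 36.9% between genes. The 3598 regions called in all 12 libraries (22.2%) were richer in promoters, at 58.8%.

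Infected libraries held 11876 ± 2584 peaks and uninfected ones 9258 ± 2076 (SD, n = 6 each), a difference of 2618 that did not pass an exact permutation test (p = 0.1, adjusted p = 0.16). The share of peaks at promoters was 29.8% ± 4.99 in infected and 36.3% ± 7.65 in uninfected libraries (exact p = 0.07, adjusted p = 0.14). Knockout libraries had narrower peaks than wild-type libraries, with a median width of 132.5 ± 7.99 bp against 186.2 ± 10.8 bp (SD, n = 6 each, exact p = 0.00216, adjusted p = 0.0173). They also covered less of the genome, 1758 ± 370 kb against 2805 ± 687 kb (exact p = 0.0108, adjusted p = 0.0433). Peak number was 10009 ± 2322 in knockout and 11125 ± 2993 in wild-type libraries (exact p = 0.494). The narrower peaks were present in all 6 knockout libraries, whose genotype also marks their library series.

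**Figure D1:**
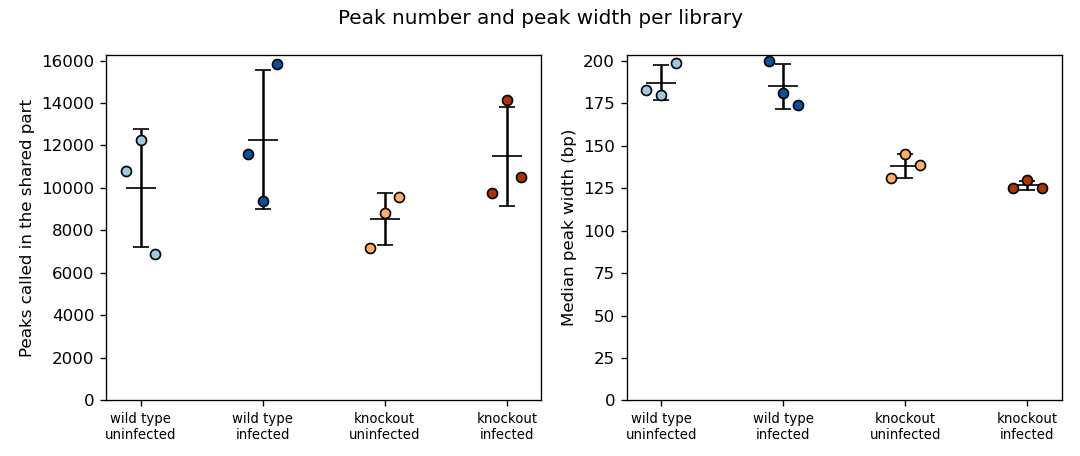
Peaks called in the shared part of the genome (left axis, number) and median peak width (right axis, bp) per library in the 4 groups; points are libraries and bars are mean ± SD (n = 3). Median widths were 132.5 bp on average in the 6 knockout libraries and 186.2 bp in the 6 wild-type libraries, with no overlap.

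Libraries of the same genotype and infection state shared more regions than libraries that differed in either. Within genotype, the mean Jaccard index was 0.673 for pairs of the same infection state and 0.609 for pairs that differed (exact one-sided p = 0.01, 400 labelings). For genotype the means were 0.634 and 0.530 (exact one-sided p = 0.00216, 924 labelings). The lowest group mean, 0.454, was that of uninfected knockout against infected wild-type libraries, and infected knockout libraries had an index of 0.588 with uninfected wild-type and 0.601 with uninfected knockout libraries.

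The first comparison takes the effect of infection averaged over the genotypes, where a call does not mean a change in each. Among promoters open in every library, that of Socs3 (chr11:117968941-117969650), a feedback inhibitor of STAT3 signalling, went from the 6.63 ± 4.73 to the 41.0 ± 10.7 percentile in wild-type pups and from 26.2 ± 10.4 to 38.4 ± 8.56 in knockout pups (SD, n = 3 each). Its rank averaged over the genotypes rose by 0.85 (SE 0.17, limma adjusted p = 0.0357). Traf3ip2, which encodes an adaptor of IL-17 receptors, went from 19.6 to 31.2 in wild type and from 11.5 to 38.4 in knockout and rose on average by 0.64 (SE 0.14, adjusted p = 0.0381). The promoter of Rara (chr11:98959516-98959979), the retinoic acid receptor alpha gene, went from 31.1 ± 7.25 to 11.04 ± 5.01 and from 41.6 ± 8.07 to 16.7 ± 1.29, an average shift of −0.75 (SE 0.15, adjusted p = 0.0357). Lgals9, which encodes galectin-9, went from 43.4 to 17.2 and from 37.6 to 21.2, a shift of −0.64 (adjusted p = 0.0417). Ctse, the gene of the protease cathepsin E, went from 43.4 to 27.7 and from 43.5 to 14.4, a shift of −0.69 (adjusted p = 0.0469).

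The test called 75 of the 3598 shared regions, 43 that rose and 32 that fell, with 747 regions at an unadjusted p under 0.05. The count was 0 with peak number as a covariate or a replicate block within genotype, 8 with 9 libraries over the wider part of the genome, and 246 or 311 when −log10 p or summit pileup was ranked. Promoters made up 20.9% of those that rose and 31.3% of those that fell. Other promoters that rose on average were Slco4c1 (an organic anion transporter), Tshr (the thyrotropin receptor), Hs1bp3, Tmem237 and Actr10. Ap1b1, which encodes a clathrin adaptor subunit, went from 77.0 to 96.6 in wild type and from 79.9 to 91.5 in knockout (shift 0.85, adjusted p = 0.0317). Gaa, the lysosomal alpha-glucosidase gene, went from 82.0 to 93.4 and from 71.5 to 89.3 (shift 0.73, adjusted p = 0.0454). Pelp1, Taf1b, Tmcc2, Rph3al, Alyref2, Galnt10 and Atxn7l1 fell on average, with shifts between −0.57 and −0.79. Tested in 1 genotype, Socs3 and Ap1b1 passed in wild type (limma adjusted p = 0.0296 each) and Slco4c1, Hs1bp3, Traf3ip2, Actr10, Pelp1 and Taf1b in knockout (adjusted p from 0.0377 to 0.0472), and none of the named promoters passed in both. Every promoter named here lost its call on the omission of at least 1 library. The count stayed near 75 without knockout uninfected library 2 (61) or wild-type uninfected library 2 (99). Each of the other 10 omissions moved it by over 1.5 times, from 4 without knockout infected library 1 to 146 without wild-type infected library 2.

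**Figure D2:**
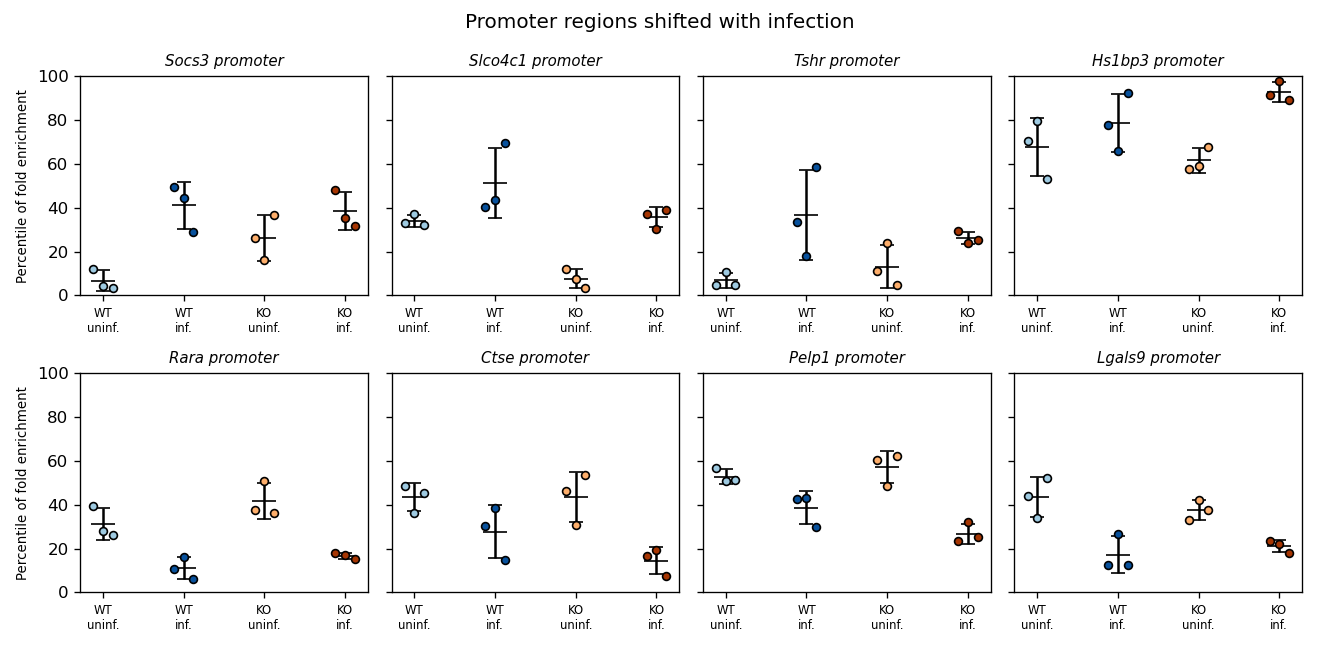
Percentile of fold enrichment among the 3598 shared regions (vertical axis) at the 4 promoters with the largest rise (upper panels) and the 4 with the largest fall (lower panels) with infection averaged over the genotypes; points are libraries in the 4 groups and bars are mean ± SD (n = 3). The mean of Socs3 went from 6.63 to 41.0 in wild type and from 26.2 to 38.4 in knockout.

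Gain and loss of whole peaks was rarer in common. In both genotypes 10 regions were gained and 0 were lost, and 5 of the 10 lay in introns and 5 between genes. The gained regions had modest fold enrichment. The highest mean percentile among all peaks of the 6 infected libraries, 56.6 ± 12.7 (SD, n = 6), was that of chr11:98058074-98058271, 4.61 kb from the start of Stac2. The others lay near Elk3 (chr10:93316927-93317141, an ETS-family transcription factor gene, 45.6 ± 31.7), in an intron of Cdh23 (chr10:60395694-60396032, 45.1 ± 17.2) and near Arhgap27 (38.3 ± 16.1). Further ones lay in introns of Rab23 (36.04 ± 23.0) and Sipa1l1 (34.8 ± 17.8) and near Peli1 (chr11:21164709-21165007, which encodes a ubiquitin ligase of Toll-like receptor signalling, 34.8 ± 11.5). The last lay in introns of Slc16a10 (24.2 ± 14.7) and of Hlx (chr1:184728831-184728997, a homeobox gene, 16.7 ± 6.48), and at chr10:43742681-43742881 (19.3 ± 13.9). The exact stratified test over 12581 regions gave 0 regions past adjustment (smallest p 0.005, adjusted p = 1), with 112 at an unadjusted p under 0.05. Of these, 109 were called more often in infected libraries. The smallest p, 0.005, is the lowest that this test can give. Over 12581 regions it could pass adjustment only if very many regions reached it, so the 0 was nearly fixed beforehand. With lists of equal length 2 regions were gained. The count rose to 27 and 30 without knockout infected library 1 or 3, 25 without wild-type infected library 2, and 18 and 38 without wild-type uninfected library 1 or 2.

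The second comparison takes infection within wild-type pups. The largest rises in rank were at a region near Tnfsf18 (chr1:161482210-161482533), the gene of the GITR ligand, from the 29.1 ± 13.5 to the 74.7 ± 16.6 percentile (SD, n = 3, shift 1.31, SE 0.28, limma adjusted p = 0.0396), and at regions near Appbp2 and in an intron of Vil1. An intronic region of Ppm1h rose from 44.9 ± 9.32 to 86.5 ± 5.28 (shift 1.26, adjusted p = 0.0177). One in Aim2 (chr1:173409101-173409395), which encodes a sensor of cytosolic DNA, rose from 28.5 ± 10.2 to 69.9 ± 11.3 (shift 1.13, adjusted p = 0.0396). Ranks fell 18.3 kb from the start of Tnfaip3 (chr10:19033735-19034009), which encodes the NF-kB inhibitor A20, from 55.9 ± 2.37 to 11.9 ± 3.29 (shift −1.34, SE 0.28, adjusted p = 0.0396). They also fell near Slc30a1, a zinc exporter gene (64.6 ± 5.75 to 17.9 ± 6.39, shift −1.32, adjusted p = 0.0296), Hivep2, Lyz1 (a lysozyme gene) and Calhm6. In all, 9 regions rose and 6 fell (403 at an unadjusted p under 0.05). The count was 0 with 9 libraries or a replicate block within genotype, 7 with peak number as a covariate, and 78 or 86 with −log10 p or summit pileup ranked. Between 0 and 9 regions were called when a wild-type library was left out: 0, 5 and 7 without infected library 1, 2 or 3, and 2, 9 and 1 without uninfected library 1, 2 or 3. By presence, 506 regions were gained and 87 lost, or 264 and 180 with lists of equal length. The omission of a library loosens the criterion, and gave 1383 and 881 gained without infected or uninfected library 2, and 211 and 364 lost without infected or uninfected library 3.

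The third comparison takes infection within knockout pups. A region near Map3k9 (chr12:81788736-81788982), a MAP kinase kinase kinase gene, rose from the 25.7 ± 13.7 to the 79.96 ± 9.32 percentile (SD, n = 3, shift 1.57, SE 0.30, limma adjusted p = 0.0377). Regions near Msgn1, at chr10:96751620-96751850 and in introns of Rps6kl1 and Tbc1d9b rose too. An intronic region of Ikzf1 (chr11:11729240-11729525), the gene of the lymphoid transcription factor Ikaros, fell from 57.0 ± 8.06 to 14.99 ± 4.44 (shift −1.23, SE 0.26, adjusted p = 0.0377); in wild-type pups it stood at 1.77 ± 0.619 without and 1.44 ± 1.54 with infection. The promoter of Bcl6b (chr11:70228962-70229172), which encodes a transcriptional repressor related to Bcl6, fell from 40.5 ± 3.18 to 4.77 ± 0.911 (shift −1.43, SE 0.23, adjusted p = 0.0203). Regions in an intron of Ltbp2, near Actg1 and at the Osgepl1 promoter also fell. In all, 35 regions rose and 23 fell (783 at an unadjusted p under 0.05). Calls numbered 0 with 9 libraries or a replicate block, 11 with peak number as a covariate, and 225 or 323 with −log10 p or summit pileup ranked. The count was 0, 0 and 6 without infected library 1, 2 or 3, 0, 4 and 0 without uninfected library 1, 2 or 3, and 14 and 129 without wild-type uninfected library 1 or 3. It was 855 over regions called in all 6 knockout libraries, in a fit of those 6 libraries alone with its own estimate of the spread. By presence, 572 regions were gained and 68 lost. With lists of equal length this turned to 234 gained and 337 lost. The omission of a library gave 1239 and 1003 gained without infected library 1 or 3, 966 and 955 without uninfected library 2 or 3. It gave 239, 185 and 162 lost without infected library 2 or uninfected library 1 or 2.

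**Figure D3:**
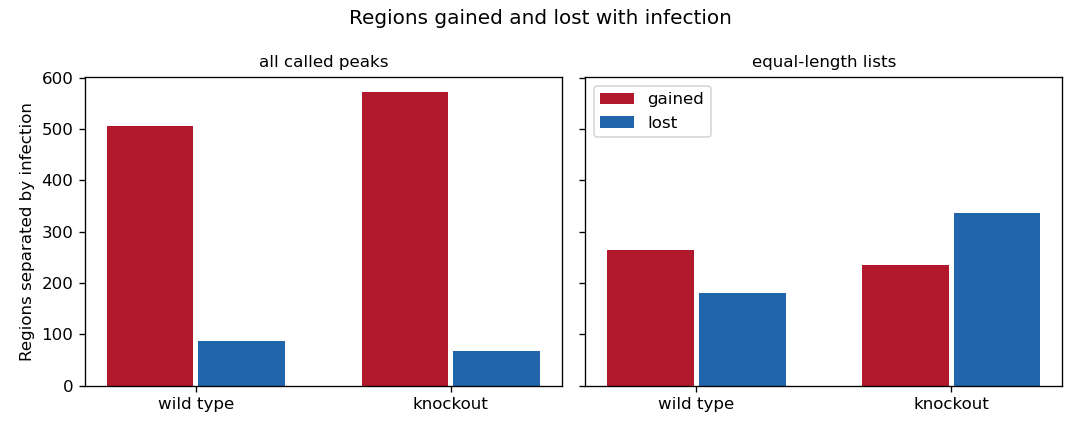
Number of regions gained or lost with infection within each genotype (vertical axis), from all called peaks (left panel) and from lists shortened to the same number of peaks per library (right panel); each bar is 1 count over 3 infected and 3 uninfected libraries. In knockout pups 572 gained and 68 lost regions became 234 and 337.

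Of the 506 and 572 regions gained in wild-type and knockout pups, 10 were the same, where 17.9 would be shared by independent sets drawn from all 16179 regions. The 3598 regions called in all libraries cannot be gained, so the number expected among the other regions is higher. Among rank shifts, 1 region rose in both, the intronic one of Ppm1h (knockout shift 0.83, limma adjusted p = 0.0493), where 0.0876 would be shared by independent sets, and 0 fell in both. Across the 3598 shared regions, which are not independent replicates, the rank shifts with infection in the genotypes had a Pearson r of 0.204 and a Spearman rho of 0.201. Of 400 labelings of the libraries 44 gave an r as high (exact one-sided p = 0.11).

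The fourth comparison tests whether infection acted differently in the genotypes. A region near Alkbh5 (chr11:60559423-60559603), which encodes an RNA demethylase, had a shift that was higher in knockout than in wild-type pups by 2.02 (SE 0.37, limma adjusted p = 0.0339). It went from the 46.8 ± 19.3 to the 14.7 ± 7.05 percentile in wild type and from 12.95 ± 2.18 to 45.2 ± 10.2 in knockout (SD, n = 3). An intronic region of Dtnb, 47.3 kb from the start of the DNA methyltransferase gene Dnmt3a (chr12:3759533-3759752), differed by 1.68 (SE 0.29, adjusted p = 0.0295), and one in an intron of Rfx4 by 1.64 (adjusted p = 0.0406). The Bcl6b promoter differed in the other direction, by −2.04 (SE 0.32, adjusted p = 0.0178), with 5.17 ± 1.40 and 16.3 ± 9.09 in wild type without and with infection. An intronic region of Rap1gap2, a Rap1 GTPase activator gene, differed by −1.91 (adjusted p = 0.0406). These 5 regions were the only calls, with 489 at an unadjusted p under 0.05. Calls numbered 0 with 9 libraries or a replicate block, 15 with peak number as a covariate, and 27 or 51 with −log10 p or summit pileup ranked. The count was 6 or 7 without knockout uninfected library 2, wild-type infected library 1 or 3 or wild-type uninfected library 3. It was 0 to 3 without each of the other 8 libraries. For Socs3 the shift was 1.33 in wild type (adjusted p = 0.0296) and 0.36 in knockout (adjusted p = 0.407), and their difference, −0.97, did not pass (adjusted p = 0.269).

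The promoters of 12 of the 18 gene lists could be tested with camera. Neutrophil, MHC class II, B cell, T and NK cell, megakaryocyte and endothelial lists had fewer than 2 members at shared promoters. In the IL-27 and STAT3 list, Socs3 and Prdm1 had average shifts over the genotypes of 0.85 and 0.46 and Stat3 one of −0.37. The mean of the list was 0.29, and it did not pass (p = 0.00578, limma adjusted p = 0.104, adjusted p = 0.415 with an estimated correlation). Its only member past the threshold over all regions was Socs3, and 2 were past it adjusted over the list alone, Socs3 and Prdm1, which encodes the repressor Blimp-1. Among erythroid promoters, Slc4a1 and Sptb had shifts of −0.48 and −0.30 (list mean −0.37, adjusted p = 0.233). All 6 interferon-stimulated promoters, Rsad2 and Cmpk2 among them, were short of the threshold, 3 with a shift above and 3 below 0 (mean −0.08, adjusted p = 1). The 5 type II interferon promoters had shifts below 0 (mean −0.18, adjusted p = 0.765), where Igtp and Irgm2 share 1 region. So had 6 of 7 NF-kB and early response promoters (mean −0.14, adjusted p = 0.765) and 6 of 7 cell cycle promoters (mean −0.15, adjusted p = 0.765). Adjusted over the list alone, 2 cell cycle members passed, Birc5 with a shift of 0.42 and Mcm3 with −0.58. So did 1 of 2 innate defence members, the decoy receptor gene Il1r2 with 0.52 (list mean 0.10, adjusted p = 0.88). Means were 0.12 for macrophage identity (Cd68, Lyz2, Slc40a1, adjusted p = 0.765) and −0.20 for housekeeping (adjusted p = 0.765). They were −0.13 for phagocytosis, −0.15 for inflammatory cytokines and −0.01 for glycolysis (adjusted p = 1 each). For glycolysis camera gave the opposite direction to the mean. No list passed for infection averaged over the genotypes, in wild type (lowest adjusted p = 0.0828) or in knockout (lowest adjusted p = 0.583). Adjusted only over lists with 3 or more members, a choice made after the data were seen, the IL-27 and STAT3 list passed on the average of the genotypes (camera adjusted p = 0.0462). With an estimated correlation its p was 0.0231 and its adjusted p over all lists 0.415. Without wild-type infected library 2, the IL-27 and STAT3 and the erythroid lists passed on the average (adjusted p = 0.0319 each) and in wild type (adjusted p = 0.0252 each). Without wild-type infected library 3 inflammatory cytokines passed in wild type (adjusted p = 0.0493). With all libraries and an estimated correlation, the adjusted p in wild type was 0.289 for the IL-27 and STAT3 and the inflammatory cytokine lists and 0.748 for the erythroid list, which had 0.942 on the average. In lists with at least 2 members, and adjusted over the list alone, Il12b and Osm and also Prdm1 and Socs3 passed in wild type, and Il12b, Il1r2 and Nlrp3 in knockout, where over all regions only Socs3 in wild type did.

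For the difference between genotypes, 1 list passed, that of inflammatory cytokines and chemokines, which had 2 testable promoters (camera adjusted p = 0.00948, adjusted p = 0.238 with an estimated correlation). Il12b, the gene of the p40 subunit shared by IL-12 and IL-23, went from the 21.8 ± 0.951 to the 9.78 ± 3.77 percentile in wild type and from 7.90 ± 2.56 to 21.5 ± 5.81 in knockout, a difference in shift of 1.17 (SE 0.31). Osm, which encodes the cytokine oncostatin M, went from 19.9 ± 12.4 to 4.81 ± 0.413 and from 3.67 ± 1.68 to 4.55 ± 2.23, a difference of 0.84 (SE 0.37). Neither passed over all regions (adjusted p = 0.141 and 0.326), and both passed adjusted over the list alone, as did Socs3 in its list. The list had a mean difference of 1.00, and 0 lists passed without wild-type uninfected library 3. With promoters limited to 500 bp from a start site 0 lists passed, since the Il12b and Osm regions lie 818 and 884 bp away. The lists of interferon-stimulated genes (mean −0.39, adjusted p = 0.669) and of NF-kB genes (mean −0.22, adjusted p = 1) did not pass.

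Peaks in loci covered more members than the shared promoters did for most lists. No list passed the exact test after adjustment over the 18 lists, and 6 had an unadjusted p under 0.05. The lowest p that 400 labelings can give is 0.005, so a list could pass only together with other lists of low p. The lack of passing lists therefore decides little. The log2 ratio of infected to uninfected libraries was −0.28 for interferon-stimulated loci (exact p = 0.005, adjusted p = 0.09), −0.66 for erythroid loci (exact p = 0.01, adjusted p = 0.09) and 0.46 for endothelial and stromal loci (exact p = 0.015, adjusted p = 0.09). It was −0.41 for macrophage loci (exact p = 0.025), −0.28 for megakaryocyte loci (exact p = 0.035) and −0.36 for housekeeping loci (exact p = 0.045). It was 0.57 for neutrophil granule loci (exact p = 0.05) and 0.23 for B cell loci (exact p = 0.08). Ratios were −0.32 for cell cycle loci (exact p = 0.095), −0.19 for glycolysis loci (exact p = 0.105) and 0.29 for T and NK cell loci (exact p = 0.135). The other lists had an exact p of 0.265 or more: phagocytosis −0.16, inflammatory cytokines 0.11, type II interferon −0.09, IL-27 and STAT3 0.10, MHC class II −0.08, NF-kB 0.05 and innate defence 0.00. With lists of equal length the ratio was 0.12 for endothelial and stromal loci (exact p = 0.595), −0.02 for housekeeping loci (exact p = 1), −0.33 for macrophage loci (exact p = 0.11), −0.23 for interferon-stimulated loci (exact p = 0.03), 0.18 for NF-kB loci (exact p = 0.04) and 0.99 for neutrophil granule loci (exact p = 0.065). It was −0.03 for cell cycle loci (exact p = 0.845) and 0.09 for B cell loci (exact p = 0.695). With 20 kb on both sides of the gene, it was −0.13 for interferon-stimulated loci (exact p = 0.095), −0.08 for megakaryocyte loci (exact p = 0.16), −0.17 for macrophage loci (exact p = 0.05), −0.17 for type II interferon loci (exact p = 0.02) and 0.26 for neutrophil granule loci (exact p = 0.02). With 9 libraries over the wider part of the genome, it was 0.02 for macrophage loci (exact p = 0.917), 0.23 for endothelial and stromal loci (exact p = 0.1), 0.45 for T and NK cell loci (exact p = 0.0167) and 0.43 for innate defence loci (exact p = 0.05). For erythroid loci it was −0.50 with lists of equal length (exact p = 0.015), −0.61 with 20 kb (exact p = 0.02) and −0.62 with 9 libraries (exact p = 0.0167), and 0 lists passed adjustment in any of these settings. With 9 libraries the lowest possible p was 0.0167, so still more lists would have had to reach it together. Erythroid loci held 17.4 ± 1.95 peaks per 10000 in uninfected and 9.79 ± 1.09 in infected knockout libraries, and 12.9 ± 2.77 and 8.96 ± 1.57 in wild-type libraries (SD, n = 3). Without wild-type uninfected library 1, interferon-stimulated and megakaryocyte loci passed, and without library 2, interferon-stimulated loci and T and NK cell loci (adjusted p = 0.045 each).

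The last comparison sets knockout against wild-type pups, with the limit that the library series differed in the same way. In uninfected pups an intronic region of Trappc10 (chr10:78216460-78216694), which encodes a subunit of a vesicle transport complex, stood at the 98.0 ± 1.55 percentile in knockout and 33.3 ± 1.60 in wild type (SD, n = 3, shift 2.55, SE 0.24, limma adjusted p = 1.1e-05). Intronic regions of Usp32 (86.3 ± 5.21 against 14.2 ± 7.002) and Mthfd1l (74.9 against 7.94) and regions at chr12:40888421-40888649 and chr10:41006769-41007007 were also higher in knockout. Intronic regions of Srgap1 (23.4 against 85.3), Ssh2 and Map3k3, and regions near Gtf3c6 (7.25 ± 4.84 against 61.1 ± 0.210) and Parp1, a DNA repair gene, were lower. Among the regions named for infected pups, which were chosen by change in percentile, 1 lay 38.2 kb from the start of Odc1 (chr12:17505775-17506550), the ornithine decarboxylase gene. It was higher in knockout, at 63.4 ± 9.70 against 3.24 ± 2.71 in wild type (shift 2.28, limma adjusted p = 1.89e-05). Other higher regions were those of Trappc10 (2.15), at chr12:40888421-40888649, in Fam228a and in Rfx4. The promoter of Rgs18, a regulator of G protein signalling, was lower in infected knockout pups, at 5.85 ± 0.650 against 56.9 ± 9.48 (shift −1.75, adjusted p = 0.000103), as were regions in Slc22a16, Srgap1 and Adgb and near Cop1.

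In uninfected pups 441 regions were higher and 428 lower in knockout, and in infected pups 230 and 228, with 1301 and 1053 at an unadjusted p under 0.05. Of these, 129 were higher and 122 lower in both, where independent sets would share 28.2 and 27.1. The genotype shifts without and with infection, which rest on different libraries, had a Pearson r of 0.624 and a Spearman rho of 0.588 across the 3598 regions. Promoters were 57.1% of the regions higher and 25.5% of those lower in uninfected knockout pups, and 43.5% and 35.1% in infected ones. By presence, 773 regions were called only in wild-type and 537 only in knockout uninfected pups, and 818 and 309 in infected pups. The highest mean percentiles among wild-type regions were those of chr1:128705096-128705575 (76.7 ± 8.43) and an intron of Mfsd6 (75.1 ± 6.18) without infection (SD, n = 3). With infection the highest was an intron of Havcr2 (chr11:46466928-46467261), which encodes the inhibitory receptor TIM-3 (81.7 ± 2.46). Among knockout regions the highest was chr1:24612529-24613391 in both states (99.99). An intron of Rufy2 (83.7 ± 1.61) and a region 16.9 kb from the start of Cxcr4, the CXCL12 receptor gene (82.6 ± 7.50), were also high without infection. Introns of Uchl5 (82.0 ± 6.40) and the autophagy gene Atg4b (80.8 ± 5.38) were high with infection. The rank counts without and with infection, 869 and 458, were 1194 and 859 with −log10 p ranked and 1415 and 1063 with summit pileup ranked. They were 552 and 388 over the upper 75% of the regions, 1514 and 680 with 9 libraries, and 993 and 728 with peak number as a covariate. The count in uninfected pups fell to 482 and 500 without knockout uninfected library 1 or 3. In infected pups it fell to 260, 284, 284 and 224 without knockout infected library 1, 2 or 3 or wild-type infected library 1. Regions called only in wild type rose to 1199 without knockout uninfected library 2 and 2219 without wild-type uninfected library 3. With infection they rose to 1430 and 1959 without knockout or wild-type infected library 2. Regions called only in infected knockout pups rose to 638, 496 and 839 without knockout infected library 1 or 3 or wild-type infected library 3.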

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

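The splits of the libraries and the lists of equal length were fixed beforehand, and the other tests in this part, with the bounds used to read all of them, were chosen only after the results were seen.

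Regions whose shift with infection differed between the genotypes were taken from the interaction test. The difference, knockout minus wild type, was 2.02 for the region near Alkbh5, 1.68 for the region in Dtnb near Dnmt3a, 1.64 for the Rfx4 intron, −2.04 for the Bcl6b promoter and −1.91 for the Rap1gap2 intron, and 1.0 for the mean of the inflammatory cytokine promoters. Of 100 splits of the libraries, the real one and others drawn at random, 4 called at least as many regions as the real one, which is counted and called 5. Swapping the infection labels of 1 genotype turns this contrast into the infection effect averaged over the genotypes, so the splits are not all free of that effect. Calls of single regions also numbered 0 with 9 libraries or a replicate block. An arbitrary grouping of the libraries is therefore not excluded. The inflammatory cytokine list of 2 promoters passed in both settings (camera adjusted p = 0.0448 and 0.00726). With 9 libraries and an estimated correlation its adjusted p was 0.862. The splits counted regions, so they did not test the list. The highest other split called 146, with wild-type uninfected libraries 1 and 3, wild-type infected library 2 and the 3 knockout infected libraries on one side. A count that high points to a structure of the samples, which was not tested further, and the knockout part of that split is the real infection grouping.

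The excess of gained over lost regions with infection went with the number of peaks called. Of the regions separated in wild type 85.3% were gained, and in knockout 89.4%. With lists of equal length the gained share was 59.46% in wild type, inside the 50% to 68.0% that the larger side held in the other 9 splits, and 40.98% in knockout, so that lost regions were then the larger side. The larger side held 51.2% to 89.2% in the other 9 splits of the knockout libraries. Lists cut to the same length tend to balance gains and losses whatever made the full lists longer, so this test cannot tell causes apart. Longer peak lists in the infected libraries remain a candidate explanation of the excess. More open sites with infection would also lengthen a list. The background recovered from the deposited values, which rises with depth if the settings were the same, was 0.628 ± 0.157 in infected and 0.651 ± 0.127 in uninfected libraries (exact p = 0.8, n = 6 each). Median summit height was 24.5 and 24.7 fragments (exact p = 1). The genotypes differed in direction. Background was 0.684 ± 0.191 in infected and 0.623 ± 0.108 in uninfected wild-type libraries, and 0.573 ± 0.127 and 0.679 ± 0.163 in knockout libraries (SD, n = 3). Mean summit heights were 25 and 23 fragments in wild type and 24 and 26.3 in knockout. Deeper sequencing of the infected libraries shows in the averages over the genotypes in neither value, but both were higher with infection in wild type. Neither value measures depth directly, since few peaks held the background value and summit heights cover called peaks only. Read numbers and settings are not given in the sources used here, so the cause of the longer lists stays open.

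The regions whose rank differed between genotypes were set against technical differences between the libraries. Adjusting the scores for region width and promoter status left 79.98% of the calls in uninfected pups (695 of 869) and 87.99% in infected pups (403 of 458), which argues against these properties of the regions as the whole cause. The widths were those of the merged regions, the same for every library, so the narrower peaks of the knockout libraries were not adjusted for. The shortest peak in each list was 65.0 ± 3.95 bp in knockout and 92.3 ± 3.88 bp in wild-type libraries, a difference of −27.33 bp (exact p = 0.00216, n = 6 each), which fits separate processing or sequencing of the library series. Every library of a genotype belongs to the same series, so series and genotype cannot be told apart, and the effect of the receptor stays among the open explanations as untested.

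The regions whose rank, averaged over the genotypes, shifted with infection were tested against peak number. With log2 peak number as a covariate, the median absolute shift of the 75 regions went from 0.734 (SE 0.170) to 0.6383 (SE 0.186), 75 of 75 kept their sign and 0 were still called, since the shift was smaller and its error larger. Peak number as a cause and infection as a cause cannot be told apart here, because infected libraries tended to hold more peaks.

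The other splits of the libraries gave the following counts. For regions gained or lost in both genotypes, 2 of 100 splits separated as many as the real 10, the highest other 16. For rank shifts averaged over the genotypes 2 of 100 called as many as the real 75, the highest other 123. These counts include the real split, and the other splits were drawn at random from those within genotype. Labels swapped within same-numbered pairs separated as many as the 10 regions in 3 of 32 labelings, the highest other 25. An arbitrary grouping is therefore not excluded for the gained regions. For the rank shifts the share lay under 0.05, but it rests on the splits drawn, so exclusion is not claimed. The split with 123 had wild-type uninfected libraries 1 and 2, wild-type infected library 3 and the 3 knockout infected libraries on one side. Comparisons of 3 against 3 have only 10 splits, too few for a share under 0.05, and in each the real split, 1 of 10, gave the highest count. By presence, the real and highest other counts were 593 and 426 for infection in wild type, 640 and 187 in knockout, 1310 and 280 for genotype without infection and 1127 and 384 with it. By rank they were 15 and 0, 58 and 0, 869 and 0, and 458 and 0, in the same order.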

How the results depend on the processing

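Among the tests below, those with 9 libraries, with adjustment for region width and promoter status, with peak number as a covariate and with a minimum of 3 list members were chosen after the data were seen. Of 343 alternative values, 209 stayed within 1.5 times the reported count or, for differences between libraries, kept their direction and their side of the 0.05 threshold in the exact test. The other 134, all counts, moved further. A count of 0 that stayed 0 was taken as unchanged. So was the count of regions gained in both genotypes under swapped labels, which that alternative cannot change. The 209 therefore overstate how stable the results were. With lists of equal length the balance in knockout turned from more gained to more lost regions. The differences in peak number, covered length and promoter share kept direction and side with a −log10 q of 8 or more. The library similarities did so there and with lists of equal length, with a difference between −0.0645 and −0.0854 for infection and between −0.104 and −0.135 for genotype. Locus counts gave 0 lists under every alternative except the omission of libraries. The lowest possible p of that test left any list alone short of the threshold, so these zeros show little stability. The planned motif test and its 3 alternatives were not run, since no genome sequence was used. Depth is unknown, and the parts of the genome beyond the shared one limit which genes could be seen. Except where given, the cause of a change was not tested.

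With lists of equal length, 2 regions were gained in both genotypes, 264 gained and 180 lost in wild type, and 234 gained and 337 lost in knockout. When peaks had to cover 50% of a region, 3 were gained in both genotypes, 114 were lost in knockout, and 1291 (uninfected) and 1849 (infected) were called only in wild type. With a −log10 q of 8 or more, 41 were lost in wild type. With 9 libraries over the wider part of the genome, where fewer libraries loosen the criterion and more regions are tested, 116 were gained and 8 lost in both genotypes, 2400 and 540 in wild type and 1465 and 567 in knockout; 1926 and 1617 were called only in wild type or knockout without infection, and 3683 and 2142 with infection.

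For rank shifts, counts are given in the order average of the genotypes, wild type, knockout, interaction, genotype uninfected, genotype infected, against 75, 15, 58, 5, 869 and 458. Ranking −log10 p gave 246, 78, 225, 27, 1194 and 859, and ranking summit pileup 311, 86, 323, 51, 1415 and 1063. The upper 75% of the regions gave 39, 7, 33, 5, 552 and 388, with fewer regions tested. Robust weights gave 232, 24, 397, 38, 1180 and 635. The 9 libraries, which leave out those with the most peaks in the shared part, gave 8, 0, 0, 0, 1514 and 680 (limma). Adjustment for width and promoter status gave 114, 24, 66, 5, 802 and 477, and peak number as a covariate 0, 7, 11, 15, 993 and 728. Regions called in all 6 libraries of a genotype, fitted on those 6 libraries alone, gave 32 in wild type and 855 in knockout. There both the regions and the estimate of the spread differ from the main fit, so their effects cannot be told apart.

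Same-numbered libraries did not deviate together: the correlations of their deviations were −0.102, −0.242 and −0.376 in wild type and 0.0831, −0.025 and −0.071 in knockout, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. With the replicate block across the groups limma called 4, 4, 0, 0, 741 and 386 regions, and with the replicate block within genotype 0, 0, 0 and 0 for the first 4 contrasts (634, 317, 662 and 379 at an unadjusted p under 0.05). Swapping labels within same-numbered pairs, 3 of 32 labelings separated as many as the 10 regions, the highest other being 25. The block in the promoter list test kept the 1 list of the interaction (adjusted p = 0.00726) and changed no other list call.

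For promoter lists, 0 lists passed for the interaction within 500 bp of a start site, since the Il12b and Osm regions lie 818 and 884 bp away, 0 with an estimated correlation and 0 among lists with 3 or more members, where the IL-27 and STAT3 list passed on the average of the genotypes (1 list, adjusted p = 0.0462). With an estimated correlation that list had p = 0.0231 and an adjusted p of 0.415 over all lists. With 9 libraries it had 9 promoters and did not pass (camera adjusted p = 0.343). The inflammatory cytokine list passed for the interaction with 9 libraries (camera adjusted p = 0.0448), but not with an estimated correlation there (adjusted p = 0.862).

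Leaving out each library gave 10 to 38 regions gained and 0 to 2 lost in both genotypes (2 and 1 without knockout uninfected library 1 or 3), 526 to 1383 gained and 96 to 364 lost in wild type, 622 to 1239 gained and 75 to 239 lost in knockout, 798 to 2219 and 544 to 799 called only in wild type or knockout without infection, and 876 to 1959 and 338 to 839 with infection. Rank counts ranged from 4 to 146 (average of the genotypes), 0 to 15 (wild type), 0 to 129 (knockout), 0 to 7 (interaction), 482 to 887 (genotype, uninfected) and 224 to 572 (genotype, infected). Lists that passed ranged from 0 to 2 for loci, for promoters on the average of the genotypes and in wild type, 0 to 0 in knockout and 0 to 1 for the interaction. Where leaving out a library left an arm with 2, the fit pooled the spread over the groups.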

Other observations

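The loci described here were picked after their values were seen. The Nos2 locus (chr11:78920787-78960254), which encodes the inducible nitric oxide synthase of activated macrophages, held 4.5 ± 1.22 peaks in infected and 1.0 ± 1.55 in uninfected libraries (SD, n = 6 each). By group it held 4.33 ± 1.53 and 2.0 ± 1.73 in wild type with and without infection, and 4.67 ± 1.15 and 0 in knockout (n = 3). Nos2, Tbx21, Fcgr2b and Cd79b had peaks in 3 of 3 libraries of every group but uninfected knockout, where they had them in 0 of 3; that group had the lowest mean number of peaks, 8536 ± 1228. The chemokine gene Ccl4 had peaks in 3 of 3 wild-type libraries of each state, in 2 of 3 infected knockout libraries and in 0 of 3 uninfected ones. Il10, an anti-inflammatory cytokine gene, had peaks in 3 of 3 infected and 1 of 3 uninfected knockout libraries, and in 2 of 3 and 1 of 3 wild-type libraries. Among erythroid loci, Hba-a2 had peaks in 3 of 3 uninfected and 1 of 3 infected knockout libraries and in 0 of 6 wild-type libraries. The differences between groups at these loci were not tested one by one.

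Some regions followed genotype in every library: 90 were called in all 6 knockout and no wild-type library, and 86 in all 6 wild-type and no knockout library. At a mean percentile of 90 or more there was 1 such region in knockout and 0 in wild type. That region, chr1:24612529-24613391, overlaps the unprocessed pseudogenes Gm10222, Gm28438 and Gm28437, which are nuclear copies of mitochondrial DNA, and had a fold enrichment, as the authors' peak caller gave it, between 71.6 and 85.0 in the 6 knockout libraries. Reads of mitochondrial origin can align to such copies. Along the first principal component of the ranks, which held 41.0% of the variance, all 6 wild-type libraries lay above and all 6 knockout libraries below 0.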
